A study of Mus musculus with 3 samples.

How the data were processed

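Chromatin immunoprecipitation with an antibody against the thyroid hormone receptors was measured on 3 Agilent tiling arrays of 2 colours, 1 for a euthyroid and 2 for hypothyroid juvenile mouse livers. Per the labels, total input DNA was labelled with Cy3 and immunoprecipitated DNA with Cy5 on every array, with no dye swap, so a dye bias of a probe cannot be separated from enrichment. Groups and sample numbers were taken from the sample titles. The extraction text in the labels describes RNA, so how the chromatin was fixed, sheared and immunoprecipitated is not given in the sources used here.

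Per the file headers, the authors scanned the arrays and read them with Agilent Feature Extraction 10.7.3.1. The processed signals are intensity values that this program had background-subtracted and scaled with a linear dye factor for each channel, per the file headers. That factor was 38.8, 14.6 and 31.4 for the immunoprecipitate of euthyroid sample 1, hypothyroid sample 2 and hypothyroid sample 3, and 12.3, 10.4 and 10.8 for the input. The program also removed a spatial trend by multiplication, from the input on euthyroid sample 1 and hypothyroid sample 3 and from the immunoprecipitate on hypothyroid sample 2, so that the channels of the arrays were not treated alike. The log10 ratio that the deposited scanner files hold is 0 where neither channel was well above background (3.01%, 0.30% and 1.72% of probes) and was not used. The second set of deposited values, log2 ratios given per sample and again for the whole series with a largest difference of 0, correlated at an r of 1 with the log2 ratio of the median signals without background subtraction. The deposited log2 ratios are centred on a median of 0 and have an SD of 1.00 on each array, with immunoprecipitate over input as their direction. They served as an alternative.

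Of 974016 features, 6009 controls and 257 probes flagged as outliers on at least 1 array were left out, which left 967750 probes. Probes were 45 to 60 nt long, 50.4% of them 60 nt and 10.8% of them 45 nt, with a median spacing of 177 bp from start to start. The log2 ratio of the processed immunoprecipitate over the processed input was centred on the median of each array, with no loess or quantile step, since many probes of such an array can carry signal. Ratios were averaged in bins of 500 bp by probe midpoint where a bin held at least 2 probes. Of 426838 bins with a probe, 328257 (76.9%) were tested, with a median of 3 probes.

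Bins were tested with limma 3.58.1 in R 4.3.3, with a mean for each group and moderated variances. Enrichment was the mean over the 3 arrays against 0, and the difference was euthyroid minus hypothyroid, both two-sided with a threshold of 0.05 after Benjamini-Hochberg adjustment. The fit had 1 residual degree of freedom, from the pair of hypothyroid arrays, and the lone euthyroid array was assumed to vary like them. The moderation gave infinite prior degrees of freedom, so every bin took the same SD of 0.986, and a bin passed at a log2 mean at least 1.85 from 0 or a log2 difference at least 4.39 above 0. In data simulated with the same model over 328000 bins, 26% of the bins enriched by 2 on the log2 scale, 82% at 3, 98% at 4 and 100% at 6 were recovered, with 9 false calls. For the difference 2% were recovered at 3, 40% at 5, 64% at 6 and 100% at 8, with 4 false calls. Those simulated bins share a variance, and the named bins of the real arrays do not. The simulated arrays also vary independently around 0, while ratios on all 3 real arrays fell with probe length. These rates and false calls therefore hold only for the simulated setting and do not give the false calls of the real arrays.

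The named bins follow a rule set before the data were examined, except that 1 bin per tiled stretch replaced the planned 1 bin per gene, as no gene names are given. They are the 12 bins with the highest mean among those enriched and above 0 on all 3 arrays, and the 10 bins with the highest and the 10 with the lowest difference among those that passed with the euthyroid array outside both hypothyroid ones. Where every probe of a bin was below the program's limit for well above background on all arrays of a group, the difference is given as a bound, and where only some probes were below it the bound is given with their number. The lowest signal among probes well above background, or the probe's own if higher, stood for the dim group, and means were taken on the log2 scale. A dim probe could truly lie above that signal, so the bounds are nominal and no strict lower limits.

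The alternatives set before the data were examined were normexp background correction (offset 50, on the median signals that the files give), loess within arrays, scaling of the arrays, the deposited ratios, a filter on dim input, bins of 250 and 1000 bp, at least 3 probes per bin, trended and robust variances, a threshold of 0.01, a minimum of 2-fold and leaving out each array. A correction for probe length, models with a single mean for the arrays, and all work on the sharing of the highest 1% of bins were added after the data had been seen. Sharing was first looked at with fold thresholds of 2 to 16 and then with the highest 1%, which gives each array the same number of bins. It was tested by 1000 circular shifts of the bins and against the number expected in 10 by 10 classes of probe length and input brightness.

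The files give mm9 positions with neither gene names nor probe sequences. The reference table at hand belongs to another build, and no position was converted. The 21 gene lists, the promoters in the title of the series, the search for thyroid hormone response elements and the correction for GC content were planned and were not analysed here. No slide held more than 1 array, so no batch term could be fitted.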

Results

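Binding of the thyroid hormone receptors, nuclear receptors that sit on DNA both with and without their hormone, was profiled in the liver of juvenile C57BL/6 mice by chromatin immunoprecipitation on tiling arrays. A polyclonal antibody against the receptors was used, and each of the 3 arrays set the immunoprecipitated DNA of a liver sample against the total input DNA of that sample. Sample 1 was euthyroid, and samples 2 and 3 were hypothyroid. Hypothyroidism was induced through drinking water given to the dams from postnatal day 12 to day 15, with 0.05% methimazole, which blocks hormone synthesis, and 1% perchlorate, which blocks the uptake of iodide. Every pup received saline 4 h before its liver was taken. The arrays carried 967750 usable probes in 23922 tiled stretches of the mouse genome, with a median length of 9797.5 bp, and the probes were summarised in 328257 bins of 500 bp. Positions are those of the mm9 build throughout, and bins are named by position because the files pair no probe with a gene. The promoters that the title of the series names were for that reason not analysed here. Nothing in the labels says whether a sample was a single liver or a pool, so the spread between samples may be technical. The p-values of the main limma fit rest on an SD pooled over all bins from the pair of hypothyroid arrays. They measure neither the spread of a single bin nor that of the euthyroid sample.

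The input DNA was measured well on all arrays, and the immunoprecipitate was not. Between 92.1% (euthyroid sample 1) and 95.1% (hypothyroid sample 3) of probes were well above background in the input channel. In the immunoprecipitate the share was 24.3% on euthyroid sample 1, 65.4% on hypothyroid sample 2 and 29.4% on hypothyroid sample 3. The median raw brightness of the immunoprecipitate was 80, 114 and 95 on the 3 arrays, over local backgrounds of 69, 70 and 73. The log2 ratio of immunoprecipitate to input had an SD over probes of 1.64, 1.29 and 1.51, and the highest 1% of probes lay above 5.88, 2.56 and 5.67. Hypothyroid sample 2 thus had the highest median and share above background in the immunoprecipitate and the smallest SD of ratios. Its bright end was the dimmest, with the highest 1% of raw immunoprecipitate signals above 722, against 1757 on euthyroid sample 1 and 1409 on hypothyroid sample 3. The number of arrays, 3, limits the precision of every comparison. Each array came from a slide of its own, so differences between slides and between samples could not be told apart.

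The first comparison asked where the receptors were bound in the juvenile liver. Enrichment was measured against the median ratio of each array, with no mock immunoprecipitation. Over the 3 arrays, 6441 of the 328257 bins were enriched and 1343 lay below the array median (limma with Benjamini-Hochberg adjustment at 0.05, two-sided, SE 0.57 on the log2 scale for every bin). The enriched bins formed 6094 separate regions, of which 327 spanned at least 2 adjacent bins and 16 at least 3. The signal came mainly from euthyroid sample 1 and hypothyroid sample 3, with medians of 3.45 and 2.90 (log2) in these bins, against 0.51 on hypothyroid sample 2. At least 4-fold enrichment was reached by 5389 of the 6441 bins on euthyroid sample 1, by 4843 on hypothyroid sample 3 and by 186 on hypothyroid sample 2. Of the 6441 bins, 4666 were above the median of all 3 arrays, and 1097 were at least 2-fold above it on all 3. The count rested on a model in which all bins share the same variance. No bin passed with normexp background correction, with the authors' deposited ratios, with a trended and robust variance, after correction for probe length or with a single mean for all 3 arrays, and the raw counts at p under 0.05 were then 56287, 60570, 35920, 38370 and 69132. The means of the 12 bins named next, 4.83 to 5.92 on the log2 scale, were 1.10 to 3.21 with loess, 2.99 to 4.22 with normexp, 1.98 to 5.07 in 1000 bp bins and 4.36 to 6.40 after correction for probe length, which lowered the prior degrees of freedom from infinite to 9.65. Within-array loess gave a count of 26437, of which 4015 bins were among the 6441. Without euthyroid sample 1 the count was 1300, of which 933 were.

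The most enriched bins lay on many chromosomes and were bright on euthyroid sample 1 and hypothyroid sample 3 alike. The highest was on chromosome 5 from 46167001 to 46167500, with a mean log2 ratio of 5.92 ± 3.49 (SD, n = 3) and an adjusted p of 9.22e-20 in the limma fit. Its ratios were 7.44 on euthyroid sample 1, 8.38 on hypothyroid sample 3 and 1.92 on hypothyroid sample 2. A bin on chromosome 1 from 121975501 to 121976000 followed, at 5.52 ± 3.00 (SD, n = 3). Chromosome 18 from 34918501 to 34919000 gave 5.26 ± 2.69, with input above background for 1 of its 2 probes, and chromosome 11 from 66832001 to 66832500 gave 5.25 ± 3.62. On chromosome 19 the bin from 12202501 to 12203000 stood at 5.17 ± 2.67, and on the X chromosome the bin from 71575001 to 71575500 stood at 5.14 ± 2.92. The bin on chromosome 17 from 47275501 to 47276000 had a mean of 5.13 ± 2.49, and was part of an enriched region of 3 bins that ran from 47275001 to 47276500. The remaining 5 of the 12 highest bins, on chromosomes 9 (119257001 to 119257500), X (54657001 to 54657500), 5 (71485501 to 71486000), 12 (66275001 to 66275500) and 2 (84217001 to 84217500), had means from 4.83 to 5.07. In all 12 bins hypothyroid sample 2 had the lowest ratio, between 0.70 and 2.28. The SD of these bins over the 3 arrays, 2.49 to 3.62, was far above the SD of 0.99 that the shared variance of the fit assumed.

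**Figure D1:**
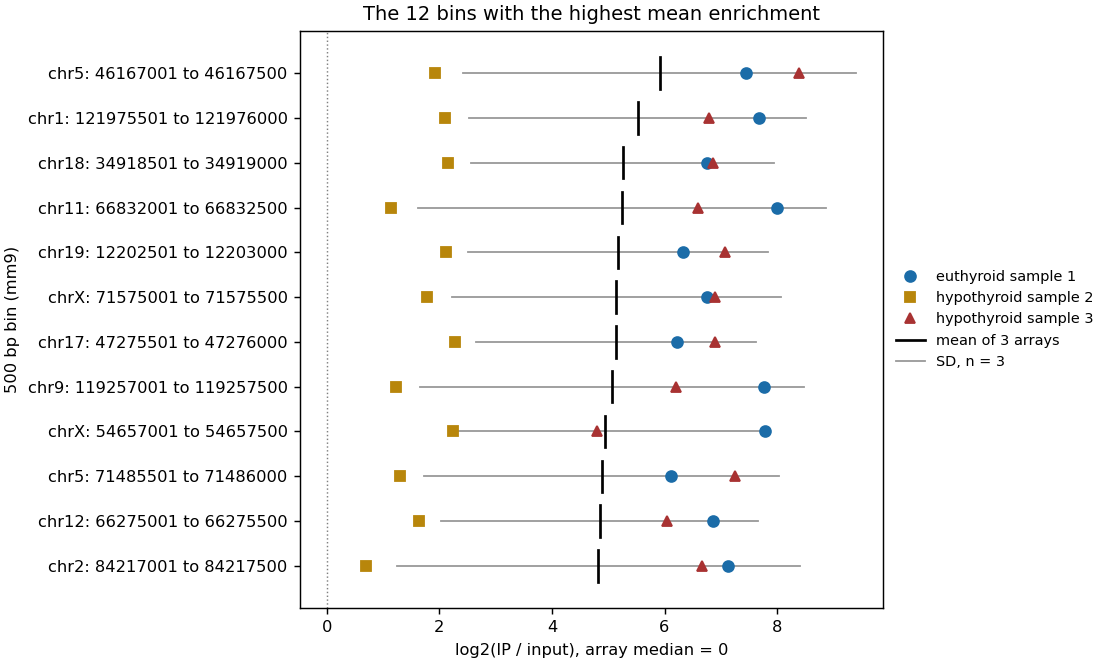
Log2 ratio of immunoprecipitate to input (x axis) in the 12 bins with the highest mean (y axis, mm9 positions); symbols are single arrays, black bars the mean of 3 arrays and grey lines the SD. Hypothyroid sample 2 lies lowest in every bin, at 0.70 to 2.28.

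**Figure D2:**
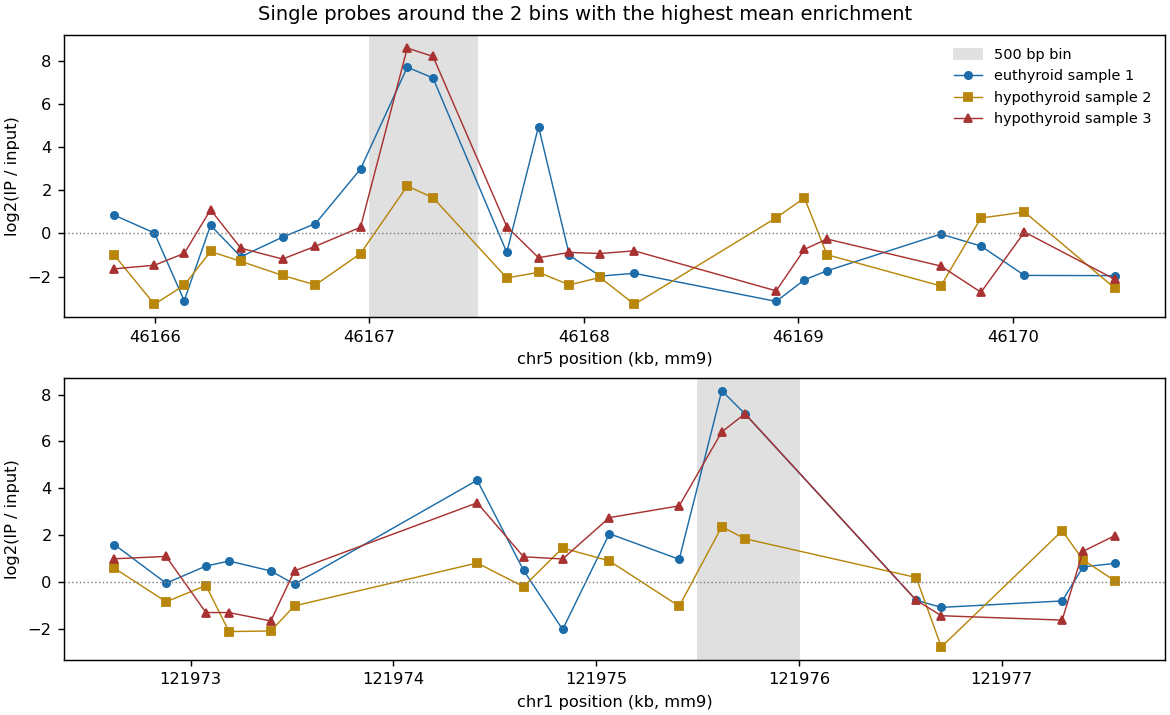
Log2 ratio of single probes (y axis) against position in kb (x axis) around the bins on chromosomes 5 (top) and 1 (bottom) with the highest means; colours and symbols are the 3 arrays and grey bands the 500 bp bins. Both probes in each band are bright on euthyroid sample 1 and hypothyroid sample 3, and ratios fall off within a few probes.

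Enriched bins were not spread evenly over the probes. Of the bins made of the shortest probes (45 to 48 nt), 4.64% were enriched, against 0.95% of the bins with 60 nt probes alone. Calls below the array median ran the other way. The shortest class had 1286 enriched bins and 0 below, while the 60 nt class had 875 enriched and 927 below. The share per chromosome ran from 1.29% on the X chromosome to 2.51% on chromosome 15 among all chromosomes but Y. On the Y chromosome 68 of 223 bins, or 30.5% (exact 95% interval 24.5 to 37.0%), were called. Input was well above background for only 29.5% to 40.3% of the Y chromosome's probes, and among bins built from probes with measured input on all arrays 0 of 49 were called (exact upper limit 7.25%). Within the 11620 tiled stretches of 8000 to 12000 bp the enriched share was nearly flat, at 1.70% to 1.99% in 5 equal parts of their length.

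Whether the arrays picked out the same bins was then asked of the highest 1% of bins on each array, 3283 bins each, a measure chosen after the data had been seen. Euthyroid sample 1 and hypothyroid sample 3 shared 562 of these bins, 17.1 times the 32.8 that independent lists would share. Matching bins on probe length and input brightness raised the expected number to 39.5. In 1000 circular shifts of the bins along the genome the arrays shared 14 to 57, giving a one-sided permutation p of 0.000999, the smallest these shifts allow, and 0.003 after Benjamini-Hochberg adjustment over the 3 pairs. The 2 hypothyroid arrays shared 51 bins, 1.55 times the expected number (permutation p = 0.003, adjusted 0.0045), and euthyroid sample 1 and hypothyroid sample 2 shared 41, or 1.25 times (permutation p = 0.103, adjusted 0.103). With the highest 5% of bins the first pair shared 3933, or 4.79 times the expected number, and the hypothyroid pair shared 1.01 times. The largest multiple possible falls as more bins are taken, so 4.79 times at 5% is not comparable with 17.1 times at 1%. Across all bins, which are not independent of each other, the ratios of euthyroid sample 1 and hypothyroid sample 3 correlated with a Pearson's r of 0.52 and a Spearman's rho of 0.59. The correlation of hypothyroid sample 2 was 0.20 (rho 0.22) with euthyroid sample 1 and 0.21 (rho 0.24) with hypothyroid sample 3.

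**Figure D3:**
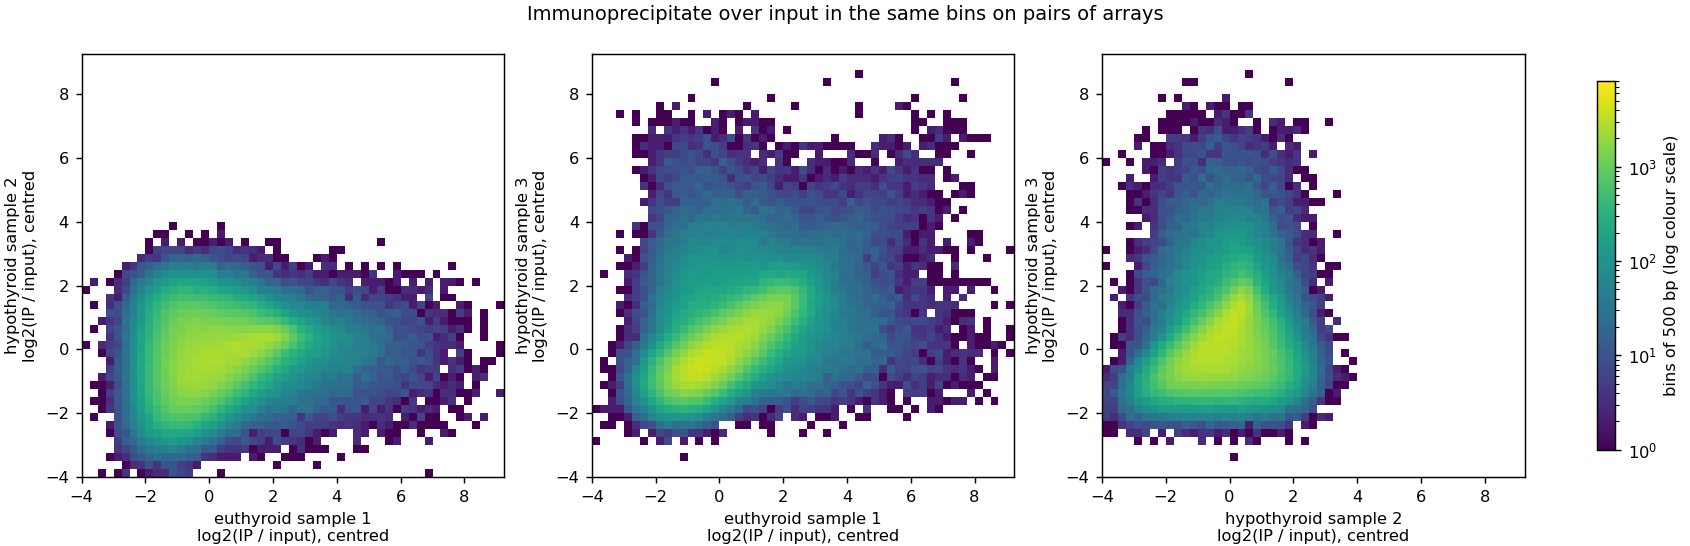
Density of 500 bp bins (colour, log scale) by their log2 ratio of immunoprecipitate to input on each pair of arrays (x and y axes, array median at 0). The bins of euthyroid sample 1 and hypothyroid sample 3 lie along a diagonal (r = 0.52), while those of hypothyroid sample 2 follow neither of the other arrays closely (r = 0.20 and 0.21).

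The shared bins lay on many chromosomes. Besides the bins on chromosomes 5, 1 and 11 given above, the strongest were on chromosome 7 from 109373501 to 109374000, with 7.51 on euthyroid sample 1 and 7.93 on hypothyroid sample 3, and on chromosome 1 from 137692501 to 137693000, with 8.27 and 6.72. A bin on the X chromosome from 92673501 to 92674000 had ratios of 7.63 and 7.01, and a bin on chromosome 9 from 71627001 to 71627500 had 7.10 and 7.34. On hypothyroid sample 2 these 4 bins lay at -1.56, -0.91, -0.50 and -1.25. The median of the 562 shared bins on hypothyroid sample 2 was -0.06, beside -0.10 for all bins, and their median rank there was the 51.8th percentile. Around the brightest probe of the shared bins the mean ratio fell from 6.54 to 0.58 on euthyroid sample 1, and from 6.06 to 0.59 on hypothyroid sample 3, at 400 to 600 bp.

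**Figure D4:**
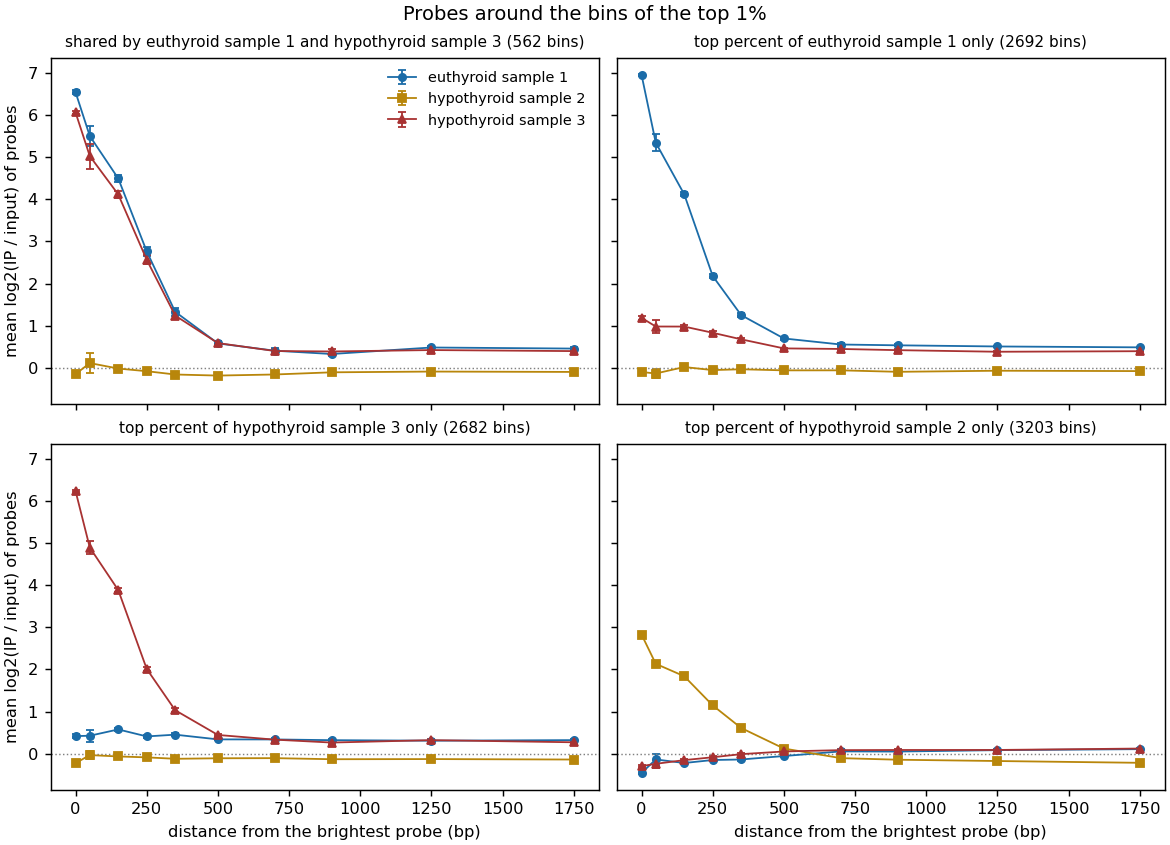
Mean log2 ratio of probes (y axis, bars are SE over probes) against distance in bp from the brightest probe (x axis), for bins among the highest 1% of both euthyroid sample 1 and hypothyroid sample 3 or of a single array (panels). The centre is high by choice of the bin on the array or arrays that define it; in the shared bins hypothyroid sample 2 stays near 0 (-0.15 at the centre).

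The second comparison asked whether binding differed between the thyroid states. The ratio on the single euthyroid array was above that of the hypothyroid samples in 1636 bins and below it in 173 (limma, Benjamini-Hochberg adjustment at 0.05, two-sided, SE 1.21 on the log2 scale for every bin). In the higher set the median log2 ratio was 5.19 on euthyroid sample 1, -0.47 on hypothyroid sample 2 and -0.05 on hypothyroid sample 3. In the lower set the medians were -1.84, 1.18 and 5.69, so that hypothyroid sample 3 carried most of that set. Of those 173 bins, 163 were over 8-fold enriched on hypothyroid sample 3 and 1 on hypothyroid sample 2. The single euthyroid array was assumed to vary as the hypothyroid ones did, and its own spread was not measured, so these counts do not separate thyroid state from bins bright on that array alone. With hypothyroid sample 3 taken as the single array in place of the euthyroid one, 1265 bins passed, and with hypothyroid sample 2 none did (41527 at a raw p under 0.05). No bin passed with normexp background correction (15712 at a raw p under 0.05) or with the authors' deposited ratios (11529), and 192 passed after correction for probe length, all of them higher in the euthyroid sample. That correction hardly moved the fitted differences of the 10 named lower bins, -7.45 to -5.83 against -7.43 to -5.92 before it, while the prior degrees of freedom fell from infinite to 9.65.

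The 10 named bins higher in the euthyroid sample had ratios of 7.55 to 9.35 on euthyroid sample 1, and their immunoprecipitate was largely not well above background on the hypothyroid arrays. They were chosen and ordered by the fitted difference, which rests on those dim signals, so they are given as bounds and their order is not a ranking of measured differences. A bound sets the euthyroid ratio against the lowest signal still well above background on each dim array, or the probe's own if higher. That signal is the lowest of a whole array, and a dim probe could truly lie above it. The hypothyroid arrays enter as their mean on the log2 scale. A bound is therefore nominal and no strict lower limit. In 4 bins no probe was well above background on either hypothyroid array (n = 2). In these the bound was 722-fold on chromosome 11 from 120216001 to 120216500 and 279-fold on chromosome 7 from 20160001 to 20160500. It was 263-fold on chromosome 4 from 149610001 to 149610500 and 261-fold on chromosome 6 from 17258501 to 17259000. The other 6 bins were measured in part. On chromosome 15 from 35225501 to 35226000, with 1 of 2 probes above background on hypothyroid sample 3 and none on hypothyroid sample 2, the euthyroid ratio was 9.35 and the bound 785-fold. On chromosome 7 from 73535001 to 73535500, with 1 of 3 probes above background on each hypothyroid array, the bound was 436-fold. On chromosome 10 from 24927501 to 24928000, with 1 of 2 probes above background on each, it was 377-fold. The bins on chromosomes 15 (26234501 to 26235000), 1 (66912001 to 66912500) and 7 (135660501 to 135661000) had 1 of 2 probes above background on hypothyroid sample 2 and none on hypothyroid sample 3, with bounds of 390-fold, 314-fold and 280-fold. These bounds hold for the processed signals alone and are no floor under other processing. The fitted log2 differences of the 10 bins, 9.24 to 10.12, were 3.08 to 6.11 with loess, 5.495 to 7.119 with normexp and 3.02 to 10.12 in 1000 bp bins. With the deposited ratios the differences were 6.24 to 8.54. Those ratios are scaled to an SD of 1.00 on each array, so that range cannot be read as a log2 fold beside the others. Over the whole set, 213 of the 1636 bins had no probe above background in either hypothyroid immunoprecipitate.

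The 10 named bins lower in the euthyroid sample were bright above all on hypothyroid sample 3, with ratios there of 6.07 to 7.63 against -0.15 to 2.49 on hypothyroid sample 2. In 9 of them no probe of the euthyroid immunoprecipitate was well above background. These differences too are bounds, but for 2 bins given below, and their order is not a ranking. On chromosome 17 from 28216001 to 28216500 the hypothyroid ratios were 2.49 and 7.11, a mean of 4.80 ± 3.27 (SD, n = 2). The bound over the euthyroid sample was 37.7-fold. It was 39.2-fold on chromosome 2 from 92021501 to 92022000, 32.9-fold on chromosome 9 from 74957501 to 74958000 and 24.1-fold on chromosome 3 from 32406501 to 32407000. On chromosomes 18 (68467501 to 68468000 and 85012501 to 85013000) and 2 (93705001 to 93705500) the bounds were 24.8-fold to 27.5-fold. The bins on chromosomes 14 (27292001 to 27292500) and 2 (18048501 to 18049000) gave 26.9-fold and 31.2-fold. These values are no bounds, since 1 of 2 probes on hypothyroid sample 2 was itself not well above background. On chromosome 7 from 114311001 to 114311500, with 1 of 2 probes above background in the euthyroid immunoprecipitate, the bound was 32.2-fold. All 10 rested mainly on hypothyroid sample 3. Without it the bounds of 8 bins were 2.00-fold to 7.59-fold, as values with no test, and the lowest was on chromosome 2 from 93705001 to 93705500. The other 2, on chromosome 14 and on chromosome 2 from 18048501 to 18049000, had 1 of 2 probes above background on hypothyroid sample 2 and are given no bound without sample 3. Like those above, the bounds hold for the processed signals alone: the fitted differences of these 10 bins, -7.43 to -5.92, were -4.86 to -3.54 with loess, -4.46 to -3.73 with normexp and -6.71 to -2.13 in 1000 bp bins. In 136 of the 173 bins no probe was above background in the euthyroid immunoprecipitate.

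**Figure D5:**
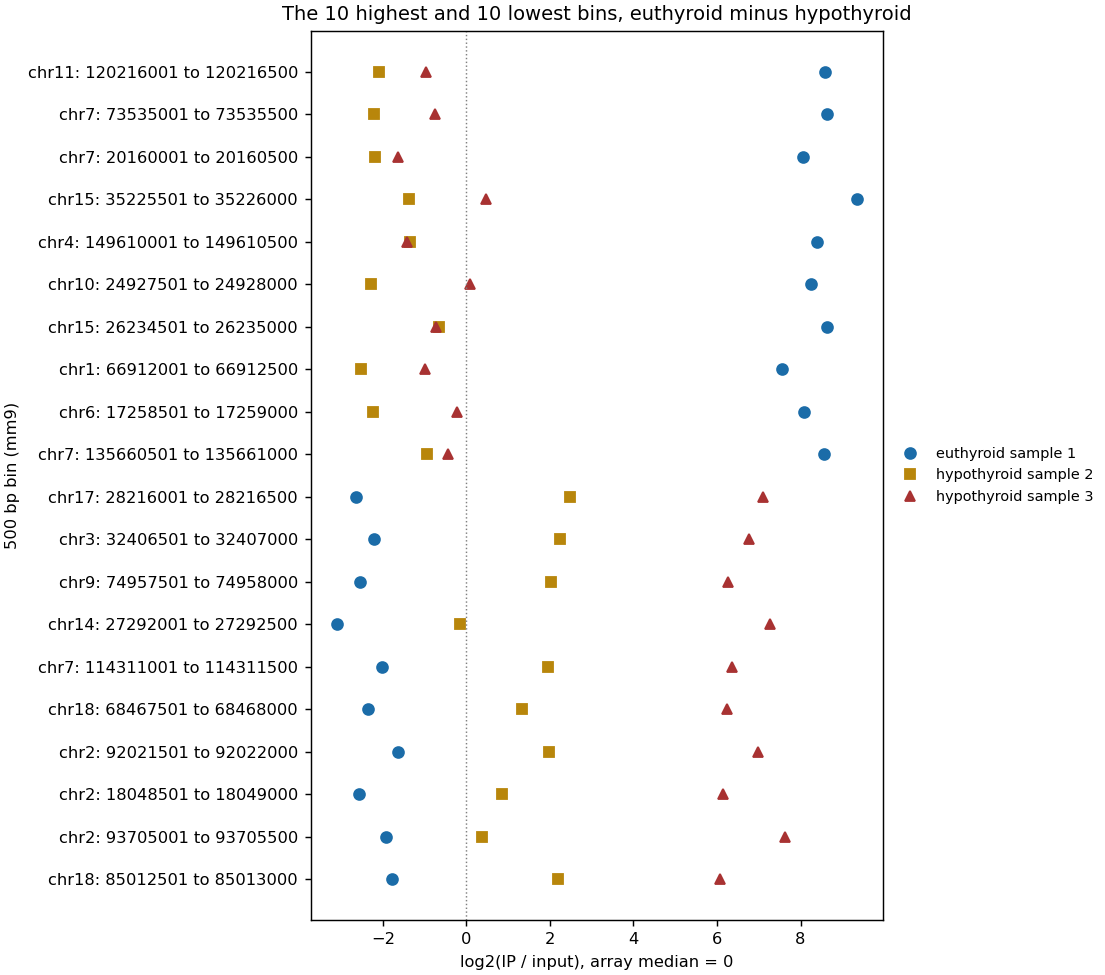
Log2 ratio of immunoprecipitate to input (x axis) on each array (symbols) in the 10 bins with the highest and the 10 with the lowest difference of euthyroid minus hypothyroid (y axis, mm9 positions). Values below 0 rest wholly or partly on immunoprecipitate not well above background, and in the lower 10 bins the hypothyroid arrays lie far apart, as on chromosome 17 with 2.49 and 7.11.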

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

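The difference between the thyroid states and its named bins were planned, and the test on the Y chromosome was set before its result was seen; the tests on single arrays, on other splits and on the sharing of bins were chosen only after the results had been seen.

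Bins that differed between the thyroid states drew attention because the test of the difference passed in 1809 of them. The 10 named bins that were higher in the euthyroid sample had fitted differences of 10.12, 10.1, 9.975, 9.799, 9.769, 9.355, 9.328, 9.317, 9.312 and 9.238 on the log2 scale. Those at 10.12, 9.975, 9.769 and 9.312 had no probe well above background on either hypothyroid array, where the bounds were 9.50, 8.13, 8.04 and 8.03, and the other 6 were measured in part, with bounds of 8.13 to 9.62. The 10 named bins that were lower had fitted differences of -7.431, -6.705, -6.692, -6.661, -6.168, -6.138, -6.126, -6.062, -5.927 and -5.922. In 9 of them the euthyroid immunoprecipitate was not well above background at any probe, and there the bounds were 4.59 to 5.29. The bins at -6.661 and -6.062 have no bound, since hypothyroid sample 2 was itself not well above background at 1 of 2 probes. The exception among the 10, at -6.168, was measured in part, with a bound of 5.01.

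The 1809 bins are 1 pattern to weigh. Bright bins that belong to a single array, whatever its group, may account for much of it: with hypothyroid sample 3 as the single array 1265 bins passed, 69.93% of the real count. Only 3 splits of 1 array against 2 exist, and 1 of them, the real one, gave as many as 1809, with 1265 as the highest other, so the splits are too few for a share under 0.05. A split with hypothyroid sample 2 as the single array gave 0 in limma, with 41527 at a raw p under 0.05, under a fit whose variances were not shared. By the size of the differences the real split did not stand out. The share of bins with a difference over 8-fold was 2.16% with euthyroid sample 1 as the single array. It was 2.32% with hypothyroid sample 2 and 2.20% with hypothyroid sample 3 in that place. An effect of thyroid state stays open: the test of the difference ran on 1 euthyroid array and cannot separate such an effect from bins bright on that array alone.

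The sharing of strong bins between euthyroid sample 1 and hypothyroid sample 3, which come from different groups, far beyond that of the 2 hypothyroid arrays (1.55 times chance), is another pattern. Probe length and input brightness do not account for it, since the number shared was still 14.24 times the number expected after matching on both. A narrower range of ratios on hypothyroid sample 2, with no added noise, would have left the order of bins in place. The shared bins had a median percentile of 51.82 there. Noise could blur the order too, so a weaker signal under noise on that array is not set aside by this value. Probes that cross-hybridise singly cannot be told apart from binding: probes within 200 bp outside the shared bins exceeded those outside random bins by 1.059 (SE 0.070, the lower of both arrays), too near the bound of 1, which was set after the profiles had been seen and tightened to need 2 SE. Binding of the receptors at these bins, with an immunoprecipitation on hypothyroid sample 2 that differed in yield or specificity, is a hypothesis that these arrays leave open, as are a mislabelled sample and carry-over between the other samples, which were not tested.

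The enriched share of 30.5% on the Y chromosome is the third pattern. Dim input is a candidate explanation, since bins whose probes all had input well above background gave 0% (0 of 49, exact upper limit 7.25%) on the Y chromosome and 1.81% elsewhere. The median input of Y chromosome probes lay at -3.102, -2.456 and -2.911 against that of all probes (log2) on euthyroid sample 1, hypothyroid sample 2 and hypothyroid sample 3. The sex of the animals is not given, and no biological explanation was tested.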

How the results depend on the processing

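The counts of called bins depended on the processing, and the sharing between arrays did so less. Correction for probe length, single-mean models and all settings for sharing were chosen after seeing the data. From 6441, the enriched count fell to 0 with normexp, the deposited ratios, trended and robust variances, probe length correction and a single mean for all 3 arrays, and moved to 26437 with loess, 3297 with scaled arrays, 4127 with at least 3 probes and 2905 at a threshold of 0.01. Leaving out an array gave 0 to 1300: 1300 without euthyroid sample 1, and with a single mean 0 without hypothyroid sample 2 and 1005 without hypothyroid sample 3. From 1809, the count that differed fell to 0 with normexp and the deposited ratios, 636 with loess, 671 with scaled arrays, 192 with probe length correction, 828 in 1000 bp bins, 981 with at least 3 probes, 406 with trended and robust variances and 987 at 0.01. Where limma gave 0, the prior degrees of freedom were finite except with trended and robust variances, and the raw counts at p under 0.05 were 35920 to 99600 for enrichment and 11529 to 15712 for the difference. The input filter (5219 and 1722), 250 bp bins (4613 and 1790) and the 2-fold minimum (6441 and 1809) left both counts within 1.5 times. The number of bins tested also changed, from 328257 in the main fit to 288380 with the input filter and 251732 in 250 bp bins. It was 217191 in 1000 bp bins and 176164 with at least 3 probes, so these counts are not shares of the same total. The 2-fold minimum could remove no bin, since every called bin already lay beyond 2-fold. Without either hypothyroid array the difference has no residual degrees of freedom. All 20 named bins kept their direction as values. Their choice fixed this, since the euthyroid array had to lie outside both hypothyroid ones. Without the euthyroid array there is no difference to test. No named bin reversed: of 173 comparisons of the 12 enriched bins 100 passed again and 73 did not, and of 103 tested comparisons each for the higher and lower bins 76 and 59 passed. Most named bins held 2 probes, and a bin with no value under a setting drops out of these tallies. With at least 3 probes only 2 enriched, 1 higher and 1 lower bin could be compared, and in 250 bp bins 4, 2 and 2. These tallies include the 2-fold minimum and the threshold of 0.01, which no named bin could fail given its value in the main fit. Leaving out an array could not reverse an enriched bin either, since each was chosen above 0 on all 3 arrays. A bin that passed again could still shrink: with loess the log2 values of the enriched, higher and lower bins were 1.10 to 3.21, 3.08 to 6.11 and -4.86 to -3.54, from 4.83 to 5.92, 9.24 to 10.12 and -7.43 to -5.92. For euthyroid sample 1 and hypothyroid sample 3 sharing stayed at 12.09 to 18.03 times chance across processing settings, and was 29.5 times for the highest 0.5% and 4.792 for the highest 5%. For the highest 5% it was 0.8055 for euthyroid sample 1 with hypothyroid sample 2 and 1.014 for the hypothyroid pair. The largest multiple possible falls as more bins are taken, so the values at 0.5%, 1% and 5% are not comparable. Beyond this and the numbers of bins tested, the cause was not tested for any of these moves. No paired analysis was possible because the groups share no sample number. The gene lists, both promoters, the response element search and GC correction, with all their alternatives, were not run; the per-sample tables equal the series table and count as 1 alternative. The dim immunoprecipitate, with 24.3% and 29.4% of probes above background on euthyroid sample 1 and hypothyroid sample 3, limits ratios near and below the median.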

Other observations

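All analyses in this part were chosen after the data had been seen.

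Regions of several adjacent enriched bins were more frequent than independent calls at a uniform rate would give, with 347 adjacent pairs of called bins against 97.6 expected. That expectation was not matched on probe length or chromosome, although the enriched share varied with both. The excess alone therefore does not show binding that spans adjacent bins. Of the 16 regions of at least 3 bins, 3 lay on the Y chromosome, among them the longest, from 2053001 to 2056000. Outside it, the longest was on chromosome 2 from 91023001 to 91025000, with mean log2 ratios of 2.90 on euthyroid sample 1, 1.40 on hypothyroid sample 2 and 4.15 on hypothyroid sample 3. A region on chromosome 15 from 101544501 to 101546000 had 4.56, 0.36 and 3.73, and a region on chromosome 5 from 139878501 to 139880000 had 4.198, 0.94 and 3.08. On chromosome 6 from 91176001 to 91177500 the signal was that of euthyroid sample 1, at 7.44, against 0.02 and 0.40.

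Bins among the highest 1% of euthyroid sample 1 alone had a mean of 1.19 at their brightest probe on hypothyroid sample 3, above the 0.39 found 1500 to 2000 bp away, with SEs of 0.04 and 0.02 over probes. Bins among the highest 1% of hypothyroid sample 3 alone had 0.42 on euthyroid sample 1 at that probe and 0.32 at 1500 to 2000 bp, with SEs of 0.04 and 0.02. Bins among the highest 1% of hypothyroid sample 2 alone had means of -0.46 on euthyroid sample 1 and -0.30 on hypothyroid sample 3 at that probe, against 0.11 and 0.12 at 1500 to 2000 bp. These bins were chosen for lying outside the highest 1% of the other arrays, which lowers those means. With 8-fold enrichment as the measure, euthyroid sample 1 and hypothyroid sample 3 shared 1544 bins against 187 expected, and with 16-fold enrichment 537 against 31.2, while hypothyroid sample 2 had 94 bins over 8-fold and 0 over 16-fold.

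The input channel did not set hypothyroid sample 2 apart in the same way. Across single probes, Spearman's rho of the input was 0.90 between the hypothyroid arrays, 0.81 between euthyroid sample 1 and hypothyroid sample 3, and 0.76 between euthyroid sample 1 and hypothyroid sample 2. Median log2 ratios fell with probe length on all 3 arrays, from 1.72 at 45 nt to -0.54 at 60 nt on euthyroid sample 1, from 0.42 to -0.40 on hypothyroid sample 2 and from 1.32 to -0.49 on hypothyroid sample 3. After correction for probe length Pearson's r across bins was 0.36 between euthyroid sample 1 and hypothyroid sample 3, and 0.07 and 0.10 for the pairs with hypothyroid sample 2.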
